A study of Homo sapiens with 30 samples.

How the data were processed

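Values were the intensities that the authors deposited, 1 per probe set and array, for 30 arrays in 15 groups of 2, and no raw file was used. The deposited intensities were linear and scaled to a common level, with trimmed means from 148.8 to 149.5 (2% left out at each end) and medians from 34.3 to 42.5, so they were taken as deposited without further normalization. The software, background treatment and scaling that the authors used were not stated in the files, and the files held no detection calls.

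Intensities were transformed to log2 after adding 6.8, the median over arrays of the 20th percentile, and every fold change here is a ratio of intensity + 6.8. Of 12626 measured features, 67 array controls were left out, and of the other 12559 probe sets 10943 carried a single gene symbol, 546 several and 1070 none. Probe sets in the upper 70% by mean over all arrays were tested, 8791 in number, for 6215 genes. A gene was represented by its brightest probe set, and probe sets with several symbols or none were counted but not named. No genome sequence was at hand, so no coordinates are given. The progesterone receptor gene PGR lay below the filter and was not tested, and LDLR had no probe set of its own.

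Differences were tested with limma 3.58.1 in R 4.3.3, in a fit of a mean per group over all 30 arrays, with moderated variances, a variance trend and Benjamini-Hochberg adjustment over the probe sets of a comparison. A probe set was called at an adjusted p under 0.05. Chance gives a share of 0.05 of unchanged probe sets an unadjusted p under 0.05. The fit had 15 residual degrees of freedom and a prior worth 6.00, or 21.0 in total. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

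Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists, and checked with the correlation estimated from the data and with fry. A list needed 5 tested members. The lists were oestrogen-induced genes (35 tested of 45 listed), oestrogen-repressed genes (28 of 35), G1/S and replication (37 of 40), G2/M and mitosis (34 of 39), growth inhibitors (19 of 25), apoptosis (25 of 32), cholesterol synthesis (19 of 26), fatty acid synthesis (11 of 18), lysosome (27 of 32), unfolded protein and integrated stress response (26 of 33), heat shock (20 of 24), ribosome biogenesis (26 of 34), growth factor signalling (33 of 43), coregulators of the oestrogen receptor (26 of 32), immediate-early genes (27 of 32), interferon response (22 of 31), aryl hydrocarbon receptor and NRF2 targets (21 of 30), epithelial genes (24 of 28), mesenchymal genes (11 of 25), immune cell genes (10 of 26) and ribosomal proteins (24 of 34).

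In each comparison with oestradiol alone against the control, the 12 largest rises and 12 largest falls past the threshold with the same sign in both sets could be named, and in every other comparison the 8 largest of each. Up to 6 members of a described list with the smallest p could be named as well, and ESR1, TFF1, PGR, GREB1, CTSD, MYC, CCND1, TGFB3, ERBB2, HMGCS1 and LDLR wherever measured. Groups, comparisons, lists, this rule, the filter and alternatives were fixed before data were seen, except those named next and later. Chosen after the values were seen were the array quality weights, all runs of genes, lists and shares without control B, the block for list tests, the block for runs with an array left out, the comparison of antagonists on genes called with oestradiol, the tests of a difference between times for an antagonist, and the simulation of unchanged groups with the control arrays' own spread.

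The labels put each array in set A or set B. After removal of group means, residuals of arrays of the same set correlated by more than 0.1 in 98 of 105 pairs of groups (median 0.216, lowest -0.0198, highest 0.383), and 30 of 30 arrays correlated best with their own set, so the sets were treated as a shared batch. Comparisons of all arrays were balanced over the sets, and counts with the set as a block are given where they differed by more than 1.5 times. The other alternatives were quantile normalization, an added value of 1.7 or 22.35 (the 5th or 40th percentile) in place of 6.8, no filter or the upper 40%, no variance trend, only the arrays compared, and leaving out each array in turn. Leaving out an array leaves a group of 1, which was assumed to vary like the other groups. It also sets an array of a single set against groups of both, so that the difference between the sets enters the comparison. Those runs were therefore repeated with the set as a block, which takes this difference out if it is alike in all groups, and the report gives the repeated runs. The files list the samples in 3 blocks, of control and oestradiol, of oestradiol with an antagonist and of antagonists alone. Whether the blocks were processed together is not stated, and treatment and block cannot be separated in comparisons across them.

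The procedure was tested on simulated data drawn from the means and spreads of these probe sets, with 200 of 8791 changed. Correlation between genes and a difference between the sets were left out. Every simulated array had the pooled spread, while the spread of the real control arrays was 1.40 times that. False calls against the control may therefore be understated. Of true log2 changes of 1, the procedure recovered 43.5% for E2 at 8 h against the control and 45.5% for TOT against ICI at 48 h. Of changes of 2 it recovered 95.0% and 94.5%. False calls made up 5.43%, 7.14%, 5.94% and 4.55% of calls in those 4 runs. A simulated list of 25 genes shifted by 0.5 (log2) had a camera p of 2.71e-11, and 1 of 20 unshifted lists had a p under 0.05. Shares expected for unchanged groups with shared arrays came from 100 simulations, in which no group differed from another, the oestradiol group included.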

Results

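Gene expression was measured in MCF-7, an oestrogen receptor-positive human breast cancer cell line, on 30 arrays of total RNA, with 1 array per sample. The arrays formed 15 groups of 2, and every group held an array of set A and an array of set B. Cells were controls, or had received oestradiol (E2, 10 nM), an antagonist (1 µM) or both for 8 or 48 h. The antagonists were ICI 182780 (ICI, also known as fulvestrant, a steroidal analogue of oestradiol), raloxifene (Ral, a benzothiophene) and trans-hydroxytamoxifen (TOT, a triphenylethylene). For the control, the labels give neither a time point nor a vehicle, so the same 2 control arrays served both times. Replicates are not labelled as separate cultures. The p-values thus measure the spread between these arrays, set difference included unless the set is a block. With 2 arrays per group, precision was limited. The 3 listed blocks of samples may have been processed apart. A batch difference would then enter all comparisons across them, so each antagonist against the control and each addition to oestradiol. Runs with an array left out kept the set as a block. Of 12559 probe sets, 8791 passed the intensity filter and were tested in limma.

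Oestradiol for 8 h raised TFF1, a secreted peptide gene long used as a marker of oestrogen response, to an intensity of 2138 ± 472 (mean ± SD, n = 2) from 442 ± 272 in the control arrays. That was a 5.22-fold rise with an adjusted p of 0.0364. CXCL12, which codes for a chemokine, rose 4.44-fold to 665 ± 37.1 from 152 ± 69.4 (adjusted p = 0.000106), and RAB31, a small GTPase of vesicle traffic, rose 4.84-fold to 1324 ± 283 from 273 ± 93.9. The protease gene PRSS23 reached 977 ± 532 from 160.4 ± 32.8, the carbonic anhydrase gene CA12 1630.2 ± 152 from 401 ± 20.9, and IGFBP4, a binding protein of insulin-like growth factors, 2709 ± 331 from 717 ± 232. Rises also included the dioxin-responsive monooxygenase gene CYP1A1 (5.61-fold), the calcitonin receptor gene CALCR (65.7 ± 15.8 from 8.75 ± 9.69) and the elongase gene ELOVL2 (399 ± 116 from 82.1 ± 6.51). Falls were led by the interleukin receptor gene IL1R1, 3.71-fold lower at 31.6 ± 15.6 against 137 ± 64.9 (adjusted p = 0.0202), and included MMD, TTC9 and the pro-apoptotic BIK with log2 changes of -1.81, -1.62 and -1.46. The growth-inhibitory ligand TGFB3 fell to 374 ± 15.3 from 677 ± 75.9, and the receptor tyrosine kinase gene ERBB2 changed by -0.98 (log2). The receptor's own gene ESR1 stood at 213 ± 15.8 against 232 ± 21.8 (adjusted p = 0.853), and the cell cycle driver CCND1, the protease gene CTSD and the sterol synthesis gene HMGCS1 had adjusted p-values of 0.515, 0.709 and 0.825. GREB1, an oestrogen-responsive growth gene, had a log2 difference of 2.34 with an adjusted p of 0.067, and MYC a difference of 0.74 (adjusted p = 0.223) that was 1.49 in set A and -0.00 in set B.

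The oestrogen-induced list had 12 of 35 members up, 0 down and 23 not past the threshold, or 25 up when adjusted over the list alone. Its median log2 change was 0.89 (camera adjusted p = 3.16e-21, and adjusted p = 0.000198 with an estimated correlation). Its risers included the corepressor gene NRIP1 (1.73), the ubiquitin ligase gene SIAH2 (1.38) and the endoplasmic reticulum gene WFS1 (1.07). Of the 28 members of the oestrogen-repressed list 6 fell and 1 rose, CYP1B1, which does not do what the list's name says. Adjusted over the list alone, 8 fell (median -0.55, camera adjusted p = 2.88e-05, adjusted p = 0.00427 with an estimated correlation). Ribosome biogenesis genes moved up, with 6 of 26 called, among them the nucleolar NOP16 (707 ± 40.02 from 416 ± 9.48), NOLC1 and RRS1. When adjusted over the list alone 14 rose (median 0.40, adjusted p = 3.61e-10, and adjusted p = 0.000198 with an estimated correlation). Among 20 heat shock genes the immunophilins FKBP5 and FKBP4 rose by 1.21 and 0.80, with 6 up adjusted over the list alone (adjusted p = 3.53e-05, and adjusted p = 0.0189 with an estimated correlation). In the G1/S and replication list 0 of 37 genes were called, although the list's median was 0.45 (camera adjusted p = 0.00095, and adjusted p = 0.848 with an estimated correlation). For lysosome genes the median was -0.23, with the glycosidase gene GLA up (0.72) and the sphingomyelinase gene SMPD1 down (-1.06), and camera gave 0.048 (adjusted p = 0.848 with an estimated correlation).

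In all, 87 probe sets rose and 64 fell at 8 h, each with the same sign in both sets, and with the set as a block 211 rose and 221 fell. Without control A, control B, the E2 array of set A or that of set B, the block's 432 became 1853, 160, 265 or 114. Of 52 called genes open to naming, 34 kept their call without control B, including TFF1 (adjusted p = 7.82e-05), PRSS23 (0.00177), CYP1A1 (0.00373) and BIK (0.0107) but not ERBB2 (0.222), while MYC passed (0.00265).

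After 48 h of oestradiol, the interleukin receptor gene IL1R1 stood at 6.05 ± 4.45 against 137 ± 64.9 in the control arrays, with an adjusted p of 3.19e-05. The lower level lies below the value of 6.8 added to all intensities, so no fold is given. The adhesion molecule gene L1CAM fell 10.5-fold to 26.2 ± 3.54 from 349 ± 122. The calcium buffer gene PVALB fell 7.01-fold to 84 ± 39.7 from 599.8 ± 52.7 (adjusted p = 8.84e-07), and INHBB, an activin subunit, to 81.2 ± 17.04 from 429.9 ± 97.9. Growth-inhibitory TGFB3 was down at 238 ± 71.1 (log2 change -1.51, adjusted p = 5.96e-05), and BIK, a pro-apoptotic gene, at 54.8 ± 2.12 against 251 ± 72.8. On the rising side, the zinc-finger gene EGR3 went from 11.7 ± 6.51 to 149.9 ± 18.4 (8.71-fold, adjusted p = 0.000117) and CXCL12 from 152 ± 69.4 to 1102 ± 35.99 (7.33-fold, adjusted p = 1.01e-06). The retrotransposon-derived PEG10 rose to 227 ± 13.8 from 29.2 ± 16.2, CCN5, a matricellular gene, to 376 ± 9.33 from 72.5 ± 12.4, and NRIP1 to 620.0 ± 125 from 155 ± 70.8. TFF1 was 5.02-fold higher at 2151 ± 1008 (adjusted p = 0.0212), and GREB1 rose to 156 ± 81.5 from 19.8 ± 10.5 (adjusted p = 0.0204). ESR1 stood at 257 ± 14.2 (adjusted p = 0.78), and MYC, CCND1, CTSD and HMGCS1 had log2 differences of 0.14, 0.04, 0.26 and -0.31 that did not pass.

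At 48 h, 15 of 35 oestrogen-induced genes rose and 0 fell, among them SIAH2 (602 ± 105, adjusted p = 6.2e-06), RAB31 and CA12. Adjusted over the list alone, 18 rose (median 0.58, camera adjusted p = 5.75e-12, adjusted p = 0.00375 with an estimated correlation). The oestrogen-repressed list had 9 of 28 down, such as the stress-response factor KLF6 (129 ± 2.19 from 383 ± 53.2) and the stress-induced NDRG1 (-1.38), with CYP1B1 as its 1 rise. Of these genes 15 fell when adjusted over the list alone (median -0.80, adjusted p = 0.00062 with an estimated correlation). All 34 of 34 G2/M and mitosis genes had a positive difference (median 0.91). Calls were made for 5, including the securin gene PTTG1 (982 ± 16.8 from 326 ± 114), the kinase gene TTK and the checkpoint gene MAD2L1, or 6 adjusted over the list alone. That list passed in camera (adjusted p = 3.05e-09) but not with correlation taken from the data (adjusted p = 0.351 with an estimated correlation, and 0.0671 with the set as a block). Of 37 G1/S and replication genes only the clamp loader RFC4 rose (1.39), and the median was 0.48 (camera adjusted p = 4.31e-05, and adjusted p = 0.545 with an estimated correlation). Lysosome genes moved down, with 4 of 27 called, including SMPD1 (91.2 ± 16.7 from 271 ± 97.9) and the cathepsins CTSL and CTSA, against a rise of GLA (0.97). Adjusted over the list alone 10 fell (median -0.45, camera adjusted p = 1.4e-05, adjusted p = 0.32 with an estimated correlation, or 0.0145 with the block added). Epithelial genes also moved down, with 4 of 24 called, such as the keratin gene KRT7 (-1.94) and the surface glycoprotein gene CD24 (142 ± 56.6 from 508 ± 167). Over the list alone 5 fell (adjusted p = 0.0182 with an estimated correlation).

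Smaller shifts were seen in the heat shock list, with 3 of 20 up (median 0.33, camera adjusted p = 0.00125, adjusted p = 0.0692 with an estimated correlation, or 0.00834 with the block added). In ribosome biogenesis 3 of 26 rose (median 0.22, adjusted p = 0.0212 with an estimated correlation). Growth factor signalling genes had 2 rises and 8 falls in 33, with a camera adjusted p of 0.0909, or 0.0351 with the set as a block. Camera called none of the other lists at 48 h. In the immediate-early list (adjusted p = 0.216) 3 rose, with EGR3 first, and 4 fell, including the phosphatase gene DUSP1 (-1.44) and IER3 (75.2 ± 3.39 from 242 ± 4.60), a gene linked to cell survival. In the aryl hydrocarbon receptor and NRF2 list (adjusted p = 0.404) 2 rose and 3, the metallothioneins MT1F, MT1X and MT1H, fell. The growth inhibitor list (0.876) had 3 rises, KLF10, CCNG1 and GADD45B, the apoptosis list (0.302) 1 rise and 2 falls, and the unfolded protein list (0.216) 2 rises. Coregulators of the receptor had 1 rise and 1 fall (adjusted p = 0.833), and VIM, the intermediate filament gene vimentin, was the 1 fall among mesenchymal genes (list adjusted p = 0.779). No member was called among cholesterol (adjusted p = 0.467), fatty acid (0.833), interferon (0.857), immune cell (0.839) or ribosomal protein genes (0.217).

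The 48 h effect comprised 183 rises and 291 falls, and 444 and 553 with the set as a block. The block's 997 calls became 2010 without control A, 674 without control B, and 659 or 474 without the set A or set B array of E2. Of 71 nameable called genes, 61 kept their call without control B, among them SMPD1 (adjusted p = 0.00264), PTTG1 (0.0258), GREB1 (0.00213) and ERBB2 (0.0263, log2 change -1.17 with all arrays).

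Compared directly, 48 h of oestradiol left L1CAM 6.94-fold below its 8 h level (26.2 ± 3.54 against 234 ± 108, adjusted p = 0.00137). PVALB stood at 84 ± 39.7 against 408 ± 4.17, and the secreted chaperone gene CLU was 2.91-fold lower at 1896 ± 73.96 against 5607 ± 1286 (adjusted p = 3.65e-07). The laminin gene LAMB1 and CD24 fell by 1.55 and 1.44 (log2). PEG10 rose to 227 ± 13.8 from 63.2 ± 28.7, the repair gene DDB2 to 547 ± 119 from 191 ± 33.4 (adjusted p = 0.000186), and IGFBP5, another binding protein of insulin-like growth factors, to 288 ± 25.03 from 114 ± 8.06. G2/M and mitosis genes had a median difference of 0.81 with 0 of 34 called and 2 up when adjusted over the list alone (camera adjusted p = 1.65e-11, adjusted p = 0.348 with an estimated correlation, or 0.049 with the block added). Oestrogen-repressed genes lay lower at 48 h (median -0.29, 0 called, adjusted p = 0.0165 with an estimated correlation). So did genes of the aryl hydrocarbon receptor and NRF2 list and of ribosome biogenesis, by medians of -0.10 and -0.10 (adjusted p = 0.0165 and 0.0165 with an estimated correlation). In limma 7 probe sets rose and 17 fell between the times, or 57 and 130 with the set as a block. The block's 187 calls became 28, 165, 72 or 97 without the 8 h array of set A or B or the 48 h array of set A or B.

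**Figure D1:**
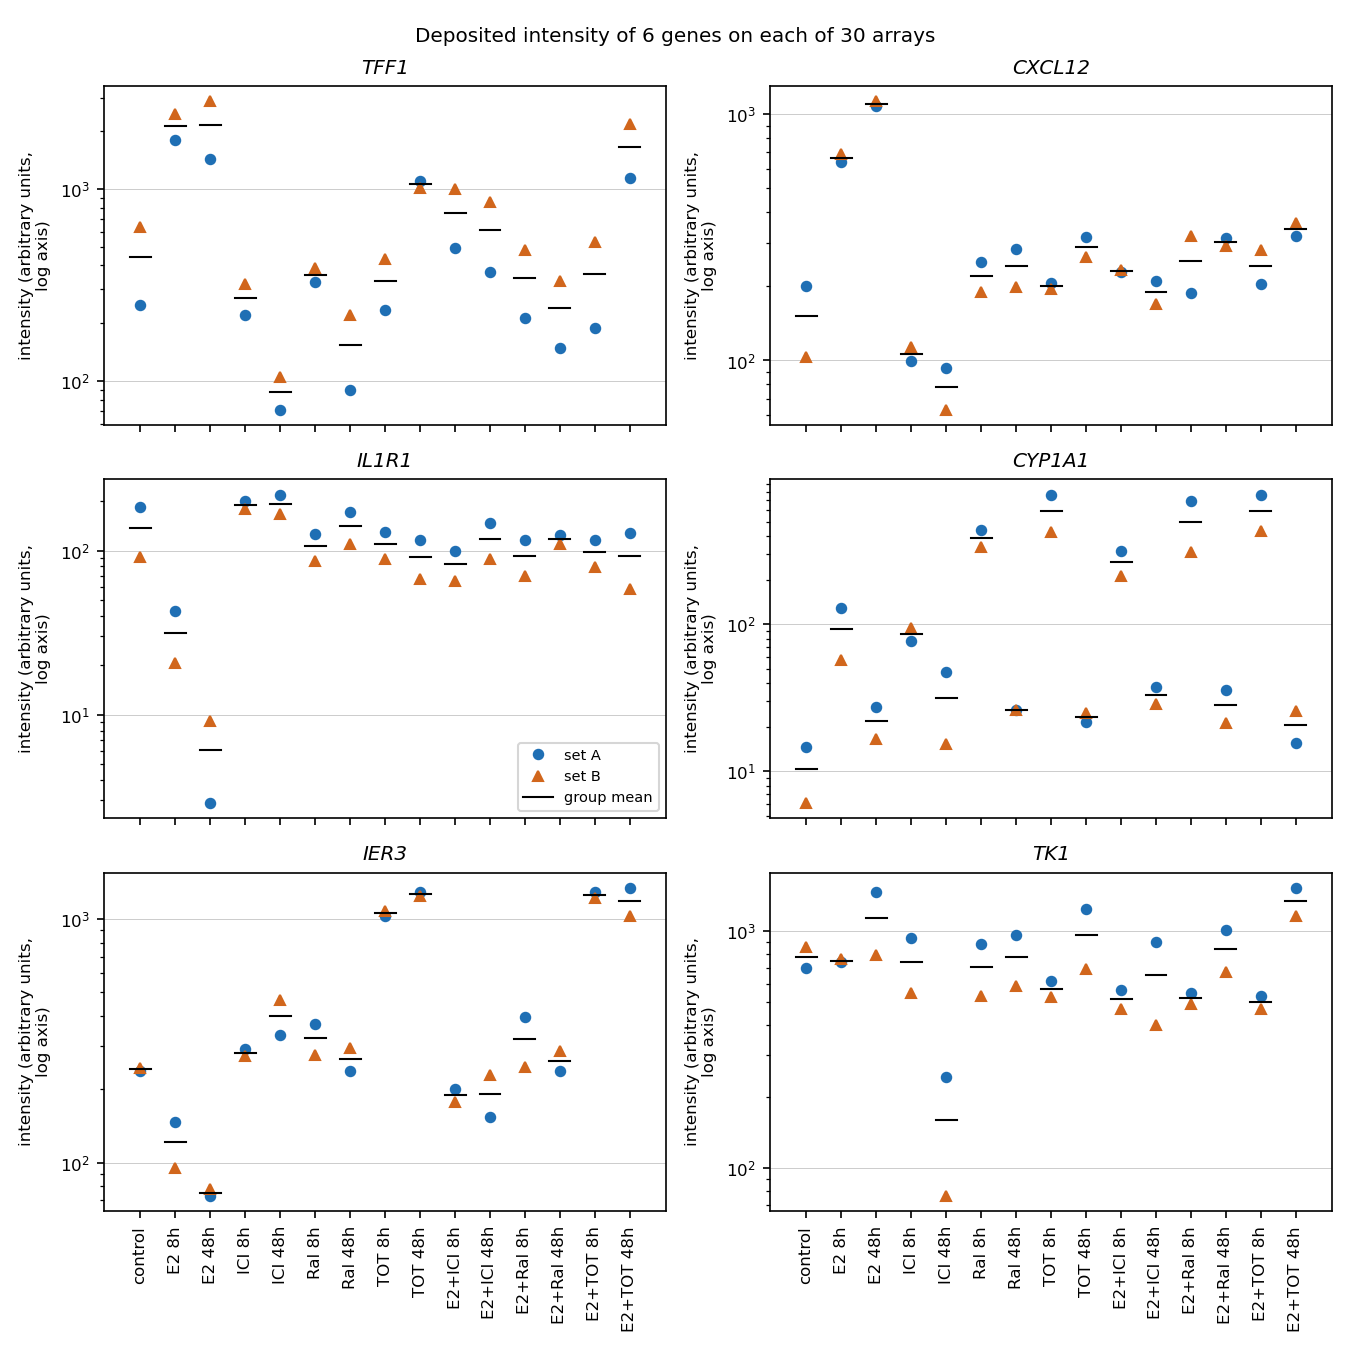
Deposited intensities (log axis) of TFF1, CXCL12, IL1R1, CYP1A1, IER3 and TK1 in the 15 groups, with a circle for the set A array, a triangle for the set B array and a bar for the group mean. TFF1 and CXCL12 were high and IL1R1 low with oestradiol, CYP1A1 peaked with Ral or TOT at 8 h, IER3 was high with TOT, and TK1 was lowest with ICI alone at 48 h.

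Given alone for 8 h, ICI raised the monooxygenase genes CYP1A1 (86.2 ± 12.2 from 10.3 ± 6.01, adjusted p = 0.0327) and CYP1B1 (125 ± 28.9 from 20.4 ± 1.77, adjusted p = 0.0015). The casein gene CSN2 and the transfer RNA methyltransferase gene TRMT1 fell (log2 changes -1.36 and -1.42). TFF1 had a log2 difference of -0.57 (adjusted p = 0.764) and ESR1 of -0.03. No oestrogen-induced gene was called, and the list's median was -0.18 (camera adjusted p = 0.0119, and adjusted p = 0.405 with an estimated correlation). Ribosome biogenesis genes had 0 calls as well (median -0.20, camera adjusted p = 0.0119, adjusted p = 0.128 with an estimated correlation). In limma 4 probe sets rose and 2 fell, with 972 at an unadjusted p under 0.05. With the set as a block 5 were called, and 1937, 4, 4 or 3 without control A, control B or the ICI array of set A or B. Without control B, CYP1A1 (adjusted p = 0.0459) and CYP1B1 (0.0142) kept their call, and CSN2 (0.705) and TRMT1 (0.639) did not.

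By 48 h, ICI alone had lowered genes of DNA replication and mitosis. The nucleotide salvage gene TK1 fell 5.43-fold to 159 ± 117 from 778 ± 116 (adjusted p = 0.0165), the mitotic activator CDC20 to 125 ± 63.4 from 602 ± 70.4, and PTTG1 to 77.2 ± 17.2 from 326 ± 114. Among G1/S and replication genes 8 of 37 fell, including the helicase subunits MCM2 (271 ± 62.6 from 789 ± 56.003), MCM5 and MCM3. When adjusted over the list alone 23 fell (median -1.08, camera adjusted p = 1.09e-17, adjusted p = 0.265 with an estimated correlation). G2/M and mitosis genes had 4 of 34 down, such as the kinesin gene KIF2C and the cyclin kinase subunit gene CKS1B, and 24 adjusted over the list alone (median -1.23, camera adjusted p = 7.47e-17, adjusted p = 0.265 with an estimated correlation). With the set as a block, the estimated correlation gave both cell cycle lists an adjusted p of 0.0467. Growth inhibitor genes had 0 called, 7 up adjusted over the list alone and a median of 0.37 (camera adjusted p = 0.0069, and adjusted p = 0.265 with an estimated correlation). Oestrogen-repressed genes had 0 called and 4 up adjusted over the list alone (camera adjusted p = 0.0257, and adjusted p = 0.225 with an estimated correlation). In ribosome biogenesis NOP16 fell (-0.87), and the list had a camera adjusted p of 0.00474 (adjusted p = 0.0958 with an estimated correlation).

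The rises with ICI at 48 h included the transcription factor gene TCF7L2 (2.22), the coagulation inhibitor gene TFPI (1.53) and the receptor coactivator gene NCOA2 (1.06). TFF1 stood at 87.8 ± 23.8 (log2 difference -2.12, adjusted p = 0.0582), oestrogen-induced genes were not called as a list (adjusted p = 0.106), and ESR1 had a difference of -0.09. Against the control 32 probe sets rose and 44 fell, or 494 and 391 with the set as a block. The block's 885 became 69 without control B, 2457 without control A, 714 without the ICI array of set A and 55 without that of set B. Of 22 named genes 12 kept a call without control B, TK1 (adjusted p = 0.00381), CDC20 (0.00151) and MCM2 (0.00751) among them, but not TCF7L2 (0.13), TFPI (0.0634) or NCOA2 (0.433).

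Raloxifene alone for 8 h raised CYP1A1 23.6-fold, to 389 ± 74.2 from 10.3 ± 6.01 (adjusted p = 3.48e-06), and CYP1B1 15.01-fold, to 400.5 ± 14.8 from 20.4 ± 1.77 (adjusted p = 1.22e-07). Both calls held without control B (adjusted p = 3.47e-06 and 1.24e-06). The cap-binding gene EIF4E and the collagen-modifying PLOD2 also rose (1.23 and 1.03) but had an adjusted p of 0.406 and 0.353 without control B, while TFF1 and ESR1 did not pass (log2 differences -0.16 and 0.02). Ribosomal protein genes had 0 calls and a median of -0.18, which was 0.03 after quantile normalization (camera adjusted p = 0.0025, adjusted p = 0.597 with an estimated correlation). In limma 7 probe sets rose and 0 fell, with 1439 at an unadjusted p under 0.05, against 6 up and 1 down after quantile normalization and 178 up and 69 down with the set as a block. The block's 247 became 2237 without control A, 8 without control B, 7 without the Ral array of set A and 8 without that of set B.

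With 48 h of Ral, the extracellular matrix gene OLFML2A rose 3.30-fold to 161 ± 42.5 from 43.1 ± 1.48 (adjusted p = 0.0122). PLOD2 rose by 1.15 (log2, adjusted p = 0.0279). TFF1 stood at 155 ± 91.6, a difference of -1.46 that did not pass (adjusted p = 0.252), and ESR1 differed by -0.10. Camera called no list (oestrogen-induced genes, adjusted p = 0.122). With the set as a block it called G2/M (0.0196) and ribosomal protein genes (0.0210), neither with an estimated correlation. In limma 2 probe sets rose and 0 fell (1337 at an unadjusted p under 0.05), against 3 up and 1 down after quantile normalization and 31 up and 34 down with the set as a block. Without control A the block's 65 became 2092, without control B 5, with OLFML2A among them (adjusted p = 0.00947) and PLOD2 not (0.153), and without the Ral array of set A or B 24 or 8.

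Hydroxytamoxifen alone for 8 h raised CYP1A1 34.7-fold to 594 ± 239 (adjusted p = 4.43e-07) and CYP1B1 17.7-fold to 472 ± 11.7 (adjusted p = 2.73e-08). IER3, an immediate-early gene that fell with oestradiol, rose 4.29-fold to 1059 ± 36.6 from 242 ± 4.60 (adjusted p = 3.24e-05). OLFML2A reached 203 ± 12.2, the amino acid transporter gene SLC7A5 1439 ± 112 and WWC1, a regulator of the Hippo pathway, 685 ± 21.8 from 268 ± 62.2. CSN2 fell (-1.47), and TFF1 had a difference of -0.32 (adjusted p = 0.828). Oestrogen-induced genes had 0 called and 5 up when adjusted over the list alone (median 0.40, camera adjusted p = 0.0211, adjusted p = 0.504 with an estimated correlation). The ribosomal protein list had a median of -0.22 that was -0.00 after quantile normalization (camera adjusted p = 0.00456, adjusted p = 0.664 with an estimated correlation). In limma 13 probe sets rose and 1 fell, or 257 and 61 with the set as a block. The block's 318 calls became 2297, 12, 20 or 15 without control A, control B or the TOT array of set A or B. Of 8 named genes 6 kept their call without control B, with ELF1 (0.231) and CSN2 (0.265) losing theirs.

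At 48 h of TOT alone, OLFML2A was 7.32-fold above the control at 359.5 ± 30.7 (adjusted p = 1.25e-06), the keratin gene KRT13 6.43-fold at 873 ± 372 against 124 ± 19.7, and IER3 5.13-fold at 1268 ± 39.7 (adjusted p = 5.58e-06). Also up were PTGES, a prostaglandin synthase gene (841 ± 246 from 179 ± 4.03), IGFBP4 (2803 ± 535), RAB31 (1225 ± 135) and the transcriptional cofactor gene CITED1 (2.21). The zinc-finger gene ZCCHC24 fell 4.61-fold to 53.9 ± 42.5 from 236 ± 15.8, and PVALB fell to 165 ± 8.70, as did the choline kinase gene CHKA (-1.79) and the pro-apoptotic BIK (-1.31), BAK1 (-1.07) and BAX (-1.03). TFF1 averaged 1061 ± 66.5, a log2 difference of 1.39 with an adjusted p of 0.2, and ESR1 differed by 0.11. Oestrogen-induced genes moved up, with 8 of 35 called, including RET and STC2, and 13 when adjusted over the list alone (median 0.44, camera adjusted p = 3.94e-07, adjusted p = 0.0643 with an estimated correlation, or 0.00796 with the block added). Among oestrogen-repressed genes 4 fell, including KLF6 (-0.98) and ERBB2 (-0.89), but CYP1B1 rose (1.83), against the list's name (median -0.31, camera adjusted p = 0.0131, adjusted p = 0.183 with an estimated correlation).

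Further list shifts with TOT at 48 h passed in camera alone. Medians were 0.40 for G1/S and replication genes (1 of 37 up, camera adjusted p = 0.00572) and 0.46 for G2/M and mitosis genes (1 of 34 up), both with adjusted p = 0.717 with an estimated correlation. In the heat shock list FKBP4 rose to 2687 ± 94.8 (list adjusted p = 0.0131, and adjusted p = 0.225 with an estimated correlation). Epithelial genes had a rise, of the secreted AGR2 (1.09), and a fall (adjusted p = 0.0131, and adjusted p = 0.225 with an estimated correlation). Lysosome genes had 2 falls (adjusted p = 0.0433, and adjusted p = 0.717 with an estimated correlation), and ribosomal protein genes a median of -0.15, or -0.03 after quantile normalization (adjusted p = 0.0131, and adjusted p = 0.717 with an estimated correlation). The comparison called 114 rises and 97 falls, or 357 and 368 with the set as a block. The block's 725 calls became 2289, 142, 213 or 212 without control A, control B or the TOT array of set A or B. Of 42 nameable called genes 23 kept their call without control B, among them KLF6 (adjusted p = 0.00808), BIK (0.0262) and CALCR (0.0385), but ERBB2 (0.36) did not.

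In the presence of oestradiol, ICI for 8 h lowered CXCL12 2.83-fold, to 231 ± 2.05 from 665 ± 37.1 with oestradiol alone (adjusted p = 0.0313). It raised the transporter gene ABCC5 to 851 ± 35.002 from 489 ± 19.6 (adjusted p = 0.0313). TFF1 stood at 750.5 ± 361 against 2138 ± 472, a log2 difference of -1.57 that did not pass (adjusted p = 0.496), and MYC differed by -1.08 (adjusted p = 0.262). As a list, oestrogen-induced genes moved down (median -0.48, 1 of 35 called, 12 down when adjusted over the list alone, adjusted p = 0.00224 with an estimated correlation). Oestrogen-repressed genes moved up (median 0.35, 0 called, 1 adjusted over the list alone, adjusted p = 0.0101 with an estimated correlation), and ribosome biogenesis genes down (median -0.24, 0 called, adjusted p = 0.00224 with an estimated correlation). G1/S and replication genes had a median of -0.22 (camera adjusted p = 0.0034, and adjusted p = 0.83 with an estimated correlation). Ribosomal protein genes had a median of -0.22 that turned to 0.01 after quantile normalization (camera adjusted p = 4.1e-06, adjusted p = 0.565 with an estimated correlation). Limma called 2 rises and 4 falls, or 14 and 15 with the set as a block. The block's 29 calls became 0, 46, 1 or 5 without the E2 array of set A or B or the E2+ICI array of set A or B.

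With ICI added to oestradiol for 48 h, IL1R1 rose to 118 ± 41.5 from 6.05 ± 4.45, with an adjusted p of 0.000112. L1CAM rose to 158 ± 73.8, CD24 to 546 ± 90.5 and TGFB3 to 525 ± 0.990, while CXCL12 fell to 190.2 ± 29.6 from 1102 ± 35.99 (adjusted p = 2.64e-05), EGR3 to 18.6 ± 0.778 and PRSS23 to 128 ± 1.77. TFF1 averaged 613 ± 346 and did not pass (-1.84, adjusted p = 0.134). Of 35 oestrogen-induced genes 9 fell and 0 rose, and 13 fell when adjusted over the list alone (median -0.46, adjusted p = 0.00247 with an estimated correlation). Rises were called for 6 of 28 oestrogen-repressed genes, including KLF6 (1.24), and for 12 adjusted over the list alone (median 0.64, adjusted p = 0.000422 with an estimated correlation). G2/M and mitosis genes had a median of -0.88 with 0 of 34 higher and 0 called (camera adjusted p = 1.67e-10, adjusted p = 0.481 with an estimated correlation). G1/S and replication genes had a median of -0.51 with 1 called (camera adjusted p = 2.42e-07, adjusted p = 0.503 with an estimated correlation). Lysosome genes moved up in camera (2 of 27, including CTSL and ASAH1, adjusted p = 0.00281, but adjusted p = 0.503 with an estimated correlation). So did the epithelial list, where CD24 was the 1 called gene (adjusted p = 0.00882, and adjusted p = 0.145 with an estimated correlation). Ribosome biogenesis moved down (median -0.25, adjusted p = 0.00385 with an estimated correlation). Counts were 110 up and 45 down, or 274 and 176 with the set as a block. The block's 450 became 235 or 272 without the E2 array of set A or B, and 226 or 166 without the E2+ICI array of set A or B.

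Raloxifene with oestradiol for 8 h lowered PRSS23 6.33-fold to 137 ± 15.7 from 977 ± 532, CXCL12 to 254 ± 93.5, SIAH2 to 189 ± 9.19 and CA12 by -1.28 (log2). It raised CYP1A1 to 501 ± 272 from 92.95 ± 50.1, CYP1B1 to 293 ± 35.1 from 107 ± 45.04 and ABCC5 to 1209.5 ± 15.5 (adjusted p = 0.00012). TFF1 was at 346 ± 189 with an adjusted p of 0.0502 (log2 difference -2.70). Oestrogen-induced genes had 5 of 35 down, and 11 adjusted over the list alone (median -0.56, adjusted p = 0.000366 with an estimated correlation). The 1 called riser of the oestrogen-repressed list was CYP1B1, with 4 up adjusted over the list alone (median 0.33, adjusted p = 0.00584 with an estimated correlation). Ribosome biogenesis genes moved down with NOP16 called (median -0.31, adjusted p = 0.000299 with an estimated correlation). For G1/S genes the median was -0.44 (camera adjusted p = 9.19e-08, and adjusted p = 0.613 with an estimated correlation). In limma 12 probe sets rose and 12 fell, or 38 and 30 with the set as a block. The block's 68 calls became 37, 41, 18 or 37 without the E2 array of set A or B or the E2+Ral array of set A or B.

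Given with oestradiol for 48 h, Ral lowered TFF1 8.89-fold to 239.7 ± 128 from 2151 ± 1008 (adjusted p = 0.00476), EGR3 to 4.65 ± 2.33 and CXCL12 to 303 ± 16.1. It raised IL1R1 to 118 ± 10.04 from 6.05 ± 4.45, TGFB3 to 616 ± 25.5 from 238 ± 71.1, and ABCC5 3.39-fold to 1069 ± 43.8 from 310.1 ± 0.495 (adjusted p = 2.52e-07). 8 of 35 oestrogen-induced genes fell, including SIAH2 (-1.66) and CCN5 (-2.33), and 11 when adjusted over the list alone (median -0.48, adjusted p = 0.019 with an estimated correlation). The oestrogen-repressed list had 3 of 28 up, TGFB3 and IL1R1 among them, and 8 adjusted over the list alone (median 0.53, adjusted p = 0.000219 with an estimated correlation). G2/M genes had a median of -0.55 with 0 called (camera adjusted p = 2.61e-05, adjusted p = 0.571 with an estimated correlation), and epithelial genes a median of 0.29 with CD24 and TSPAN8 called (adjusted p = 0.0953 with an estimated correlation). Counts were 79 up and 32 down, or 216 and 82 with the set as a block. The block's 298 calls became 193, 180, 178 or 119 without the E2 array of set A or B or the E2+Ral array of set A or B.

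Hydroxytamoxifen with oestradiol for 8 h raised IER3 10.1-fold to 1257 ± 56.5 from 121 ± 36.8 (adjusted p = 4.02e-08), along with CYP1A1 (592 ± 229) and CYP1B1 (435 ± 52.3). TFF1 fell 6.54-fold to 359 ± 242 (adjusted p = 0.0452), and PRSS23, ELOVL2, SIAH2 and CXCL12 fell by 2.53, 1.75, 1.53 and 1.44 (log2). Oestrogen-induced genes had 6 of 35 down, and 11 adjusted over the list alone (median -0.43, adjusted p = 0.000717 with an estimated correlation). The oestrogen-repressed list moved up (median 0.40, 4 up adjusted over the list alone, adjusted p = 0.00477 with an estimated correlation), with CYP1B1 its 1 called riser. Ribosome biogenesis genes had 1 of 26 down (median -0.30, adjusted p = 0.000297 with an estimated correlation), and G1/S genes a median of -0.48 (camera adjusted p = 8.2e-08, and adjusted p = 0.574 with an estimated correlation). In limma 14 rose and 14 fell, or 31 and 29 with the set as a block, against 9 up and 14 down (39.1% up) after quantile normalization. The block's 60 became 31, 48, 17 or 32 without the E2 array of set A or B or the E2+TOT array of set A or B.

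At 48 h the same pair of compounds left TFF1 at 1660.0 ± 723 against 2151 ± 1008 with oestradiol alone, a log2 difference of -0.36 with a 95% interval from -1.57 to 0.85 (adjusted p = 0.901). IER3 rose 14.4-fold to 1187 ± 222 (adjusted p = 1.23e-09), KRT13 to 1193 ± 578 from 153 ± 42.8, the cytokine signalling inhibitor gene SOCS1 to 115 ± 35.8 from 9.85 ± 5.16, and IL1R1 to 93.2 ± 48.7. SIAH2 fell to 143 ± 19.1 (adjusted p = 4.66e-07), the membrane repair gene MYOF to 294 ± 33.6 from 1289.7 ± 126, and CXCL12 to 341 ± 29.5. Within the oestrogen-induced list 3 rose and 5 fell of 35, with a median of -0.20 and no call for the list (camera adjusted p = 0.224). The oestrogen-repressed list had 2 rises, IL1R1 and TGFB3, and 4 adjusted over the list alone (median 0.31, adjusted p = 0.0357 with an estimated correlation, or 0.0657 with the block added). G2/M genes (median -0.34, camera adjusted p = 0.00352) and lysosome genes (camera adjusted p = 0.014) had 0 calls, with adjusted p = 0.74 and 0.725 with an estimated correlation. Ribosome biogenesis genes had a median of -0.15 (adjusted p = 0.0374 with an estimated correlation). In all 45 probe sets rose and 24 fell, or 125 and 94 with the set as a block. The block's 219 calls became 122, 122, 127 or 81 without the E2 array of set A or B or the E2+TOT array of set A or B.

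**Figure D2:**
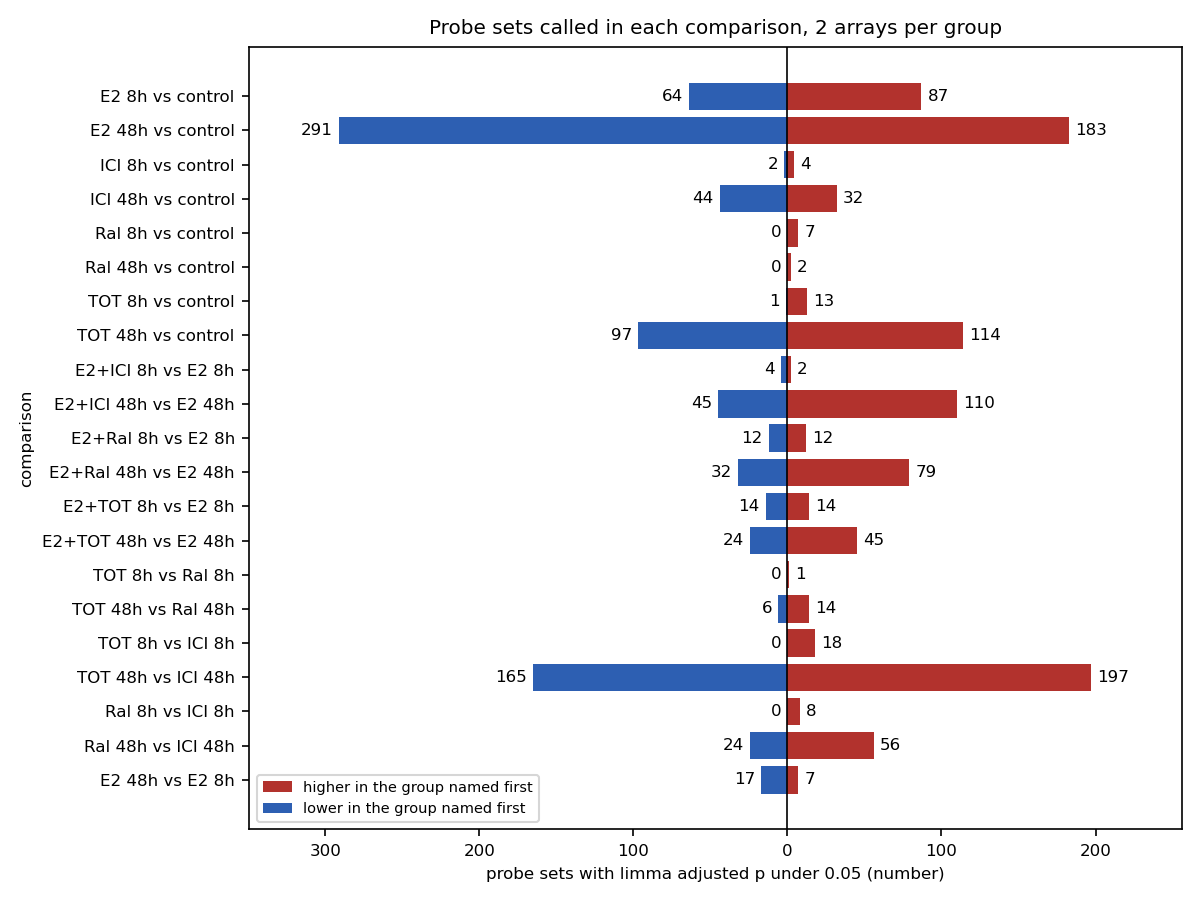
Number of probe sets called up (bars to the right) and down (bars to the left) in each of 21 comparisons at an adjusted p under 0.05. Most calls came from oestradiol or TOT at 48 h against the control and from TOT against ICI at 48 h, with 362 in the last.

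Genes called with oestradiol at either time were followed with each antagonist at the other time, so that no array was shared, and tested with limma's fry, adjusted over the 6 tests. The brightest probe set of 376 genes was called at 48 h (153 induced, such as CXCL12, and 223 repressed, such as IL1R1). Of these genes 307 moved against oestradiol in E2+Ral at 8 h (81.6%, median 0.24 in log2, adjusted p = 0.00114) and 286 in E2+TOT at 8 h (76.1%, median 0.21, adjusted p = 0.00263). With E2+ICI at 8 h 234 did (62.2%, median 0.10, adjusted p = 0.0538), a share that was 77.6% for the genes called without control B, and the share for E2+TOT at 8 h was then 84.4%. Of 115 genes called at 8 h, 93 moved against oestradiol in E2+ICI at 48 h (80.9%, adjusted p = 2.38e-05), 89 in E2+Ral (77.4%, adjusted p = 6.84e-05) and 77 in E2+TOT (67.0%, adjusted p = 0.00263). Limma called 32, 26 and 15 of them opposite to oestradiol, and 0, 0 and 3 the same way. At matched times the shares were 87.0%, 96.5% and 92.2% at 8 h for ICI, Ral and TOT, and 95.5%, 96.0% and 83.5% at 48 h. Unchanged groups sharing the E2 arrays gave 93.5% and 90.2% in simulation, so shared arrays may account for most of these shares.

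Compounds given alone were compared with oestradiol on the same genes. At 48 h, 93.4% of the 376 genes moved the same way with TOT as with oestradiol, 88.3% with Ral and 55.1% with ICI, and at 8 h the shares of the 115 genes were 93.0%, 92.2% and 67.8%. All of these contrasts share the 2 control arrays, and unchanged groups gave 97.3% at 48 h and 99.0% at 8 h in simulation with the control arrays' own spread (1.40 times the pooled spread), or 90.04% and 93.6% with the pooled spread. The covariance of log2 changes at 48 h was 0.160 for TOT, 0.126 for Ral and 0.0412 for ICI, against 0.105 in simulation, or 0.0537 with the pooled spread. TOT and oestradiol at 48 h shared 42 called rises, RAB31 and CALCR among them, and 49 falls, such as PVALB and BIK, with 2 genes called in opposite directions. No overlap of calls was simulated for unchanged groups that share the control arrays, so these numbers do not show how far the compounds agree.

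Set against the control arrays, cells given oestradiol and ICI for 48 h had 1 rise and 2 falls (16 and 13 with the set as a block, 0 and 0 without control B), with TFF1 at 613 ± 346 against 442 ± 272 and CXCL12 at 190.2 ± 29.6 against 152 ± 69.4. With Ral in place of ICI the counts were 3 and 1 (35 and 42 with the block, 4 and 0 without control B), and with TOT 125 and 177 (334 and 481, or 140 and 250 without control B). At 8 h the counts were 230 and 66 for E2+ICI (599 and 340 with the block, 9 and 0 without control B), 9 and 2 for E2+Ral (16 and 7, or 11 and 0) and 29 and 4 for E2+TOT (188 and 72, or 15 and 0).

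Between the antagonists, which share no array with one another, TOT and Ral at 8 h differed in a single gene, IER3, 3.26-fold higher with TOT at 1059 ± 36.6 against 324 ± 67.4 (adjusted p = 0.0045). The 95% interval of the log2 difference was -1.37 to 1.05 for TFF1, -0.55 to 0.27 for ESR1, -0.38 to 1.49 for CYP1A1 and -0.29 to 0.52 for TGFB3, none of which passed. Camera called no list. Limma called 1 probe set up and 0 down, with 153 at an unadjusted p under 0.05, and IER3 was not called without the Ral array of set B or either TOT array, with or without the set as a block.

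By 48 h, TFF1 was 7.20-fold higher with TOT than with Ral, at 1061 ± 66.5 against 155 ± 91.6 (adjusted p = 0.0358). KRT13 was at 873 ± 372 against 150.4 ± 8.70 (adjusted p = 0.000233), IER3 at 1268 ± 39.7 against 268 ± 41.6 (adjusted p = 6.13e-05), and the tropomyosin gene TPM1 at 1014 ± 116 against 315 ± 49.002. SOCS1, the activin antagonist gene FST, PTGES and RAB31 were higher too, by 2.01, 1.62, 1.43 and 1.29 (log2). ZCCHC24 (-1.56), the amino acid decarboxylase gene DDC (-1.32) and the retinoid receptor gene RXRA (-0.75) were lower with TOT. For ESR1 the 95% interval was -0.20 to 0.62, for CCND1 -0.38 to 0.39, for TGFB3 -0.45 to 0.37 and for MYC -0.77 to 0.43, while CTSD differed by 1.17 with an adjusted p of 0.183. The oestrogen-induced list was higher with TOT, with 3 of 35 called and 8 when adjusted over the list alone (median 0.28, adjusted p = 0.0425 with an estimated correlation). G1/S genes had a median of 0.26 with 0 called (camera adjusted p = 0.00199, adjusted p = 0.73 with an estimated correlation). Limma called 14 up and 6 down, or 23 and 14 with the set as a block. The block's 37 calls became 33, 9, 19 or 24 without the Ral array of set A or B or the TOT array of set A or B.

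Against ICI at 8 h, TOT gave higher CYP1A1 (6.22-fold, adjusted p = 0.00811), CYP1B1 (1.88 in log2), and OLFML2A (203 ± 12.2 against 32.1 ± 12.5, adjusted p = 4.01e-05). IER3 was higher as well (1059 ± 36.6 against 283 ± 13.01), as was IGFBP4 (1787 ± 381 against 517 ± 32.7). TFF1 and ESR1 did not pass, with 95% intervals of -0.96 to 1.47 and -0.51 to 0.31. Oestrogen-induced genes were higher with TOT, with 3 of 35 called and 9 adjusted over the list alone (median 0.41, adjusted p = 0.000899 with an estimated correlation). So were ribosome biogenesis genes, with RRS1 called and 4 adjusted over the list alone (median 0.33, adjusted p = 2.52e-05 with an estimated correlation). Immediate-early genes had a median of 0.12 with 1 called (adjusted p = 0.0475 with an estimated correlation). Oestrogen-repressed genes had a median of -0.21 although their 1 called gene, CYP1B1, was higher (camera adjusted p = 0.0302, and adjusted p = 0.101 with an estimated correlation). Ribosomal protein genes had a median of -0.11 that turned to 0.01 after quantile normalization. In limma 18 probe sets were higher and 0 lower (308 at an unadjusted p under 0.05), or 26 and 2 with the set as a block. The block's 28 calls became 16, 17, 15 or 15 without the ICI array of set A or B or the TOT array of set A or B.

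The widest difference between antagonists was that of TOT and ICI at 48 h. TFF1 was 11.4-fold higher with TOT (1061 ± 66.5 against 87.8 ± 23.8, adjusted p = 0.00104). TK1 stood at 966 ± 384 against 159 ± 117, the transcription factor gene MYBL2 at 602 ± 179 against 93.2 ± 81.7, and the replication initiation gene CDC45 at 98.7 ± 54.3 against 4 ± 2.26. Of 37 G1/S and replication genes 23 were higher with TOT, MCM2 (1.88) and MCM3 (1.63) among them, or 34 adjusted over the list alone (median 1.58, adjusted p = 0.0407 with an estimated correlation). G2/M and mitosis genes had 20 of 34 higher, including PTTG1 (2.50) and CKS1B (1.60), or 33 adjusted over the list alone (median 1.73, camera adjusted p = 2.32e-29, adjusted p = 0.0518 with an estimated correlation, or 0.00297 with the block added). The cyclin kinase inhibitor gene CDKN1A was lower with TOT (406 ± 57.1 against 720.5 ± 96.7), as was FOXO3 (-1.23). The growth inhibitor list had 4 lower and GADD45B higher (median -0.55, camera adjusted p = 0.00267, adjusted p = 0.145 with an estimated correlation). For ESR1 and CCND1 the 95% intervals were -0.21 to 0.61 and -0.00 to 0.77.

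Oestrogen-induced genes were higher with TOT than with ICI at 48 h, 11 of 35, including IGFBP4 (2.55) and RAB31 (2.51), or 14 adjusted over the list alone (median 0.55, adjusted p = 0.00223 with an estimated correlation). Oestrogen-repressed genes were lower, 6 of 28, KLF6 and BIK among them, against 1 higher, CYP1B1, or 14 adjusted over the list alone (median -0.74, adjusted p = 0.00189 with an estimated correlation). Ribosome biogenesis had 3 higher (adjusted p = 0.00189 with an estimated correlation), heat shock 2 higher (0.0275), and epithelial genes 1 higher and 2 lower (0.0275). Lysosome genes had 3 lower (median -0.37, camera adjusted p = 0.000996, adjusted p = 0.499 with an estimated correlation, or 0.0378 with the block added). Limma called 197 probe sets higher and 165 lower, or 419 and 395 with the set as a block. The block's 814 calls became 517, 446, 378 or 581 without the ICI array of set A or B or the TOT array of set A or B.

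Raloxifene at 8 h gave higher OLFML2A than ICI (115 ± 4.03 against 32.1 ± 12.5, adjusted p = 0.0175), and higher CYP1B1 (1.65), IGFBP4 (1.54) and SLC7A5 (1.23). CYP1A1 differed by 2.08 with an adjusted p of 0.119. The 95% intervals of TFF1 and ESR1 were -0.80 to 1.62 and -0.37 to 0.45. Oestrogen-induced genes were higher with Ral (1 of 35 called, 8 adjusted over the list alone, median 0.38, adjusted p = 0.00153 with an estimated correlation), and so were ribosome biogenesis genes (0 called, median 0.35, adjusted p = 6.84e-05 with an estimated correlation). Limma called 8 probe sets higher and 0 lower (279 at an unadjusted p under 0.05), or 16 and 1 with the set as a block. The block's 17 calls became 8, 12, 8 or 7 without the ICI array of set A or B or the Ral array of set A or B.

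At 48 h the same pair differed most in cell cycle genes. PTTG1 was at 495 ± 118 with Ral against 77.2 ± 17.2 with ICI (adjusted p = 0.00486), TK1 at 776 ± 268 against 159 ± 117 (adjusted p = 0.0106), and CDC20 and KIF2C were higher by 2.18 and 1.99 (log2). Of G1/S and replication genes 9 of 37 were higher with Ral, or 31 adjusted over the list alone (median 1.26), and of G2/M and mitosis genes 9 of 34, or 32 adjusted over the list alone (median 1.58). Both passed in camera (adjusted p = 4.02e-30 and 4.94e-32) and had adjusted p = 0.057 with an estimated correlation, or 0.00443 with the block added. Oestrogen-induced genes had 4 of 35 higher, IGFBP4 (1864 ± 245 against 469.8 ± 7.92) among them (median 0.23, camera adjusted p = 8.22e-06, adjusted p = 0.057 with an estimated correlation, or 0.00932 with the block added). Oestrogen-repressed genes had 1 lower, and 8 adjusted over the list alone (median -0.49, adjusted p = 0.00427 with an estimated correlation), and ribosome biogenesis genes 0 called (adjusted p = 0.00458 with an estimated correlation). VIM was lower with Ral (-2.06), as were LAMB1 (-1.12) and BCAS1 (-1.51), while TFF1 differed by 0.67 (95% interval -0.54 to 1.88, adjusted p = 0.758) and ESR1 had an interval of -0.42 to 0.40. Limma called 56 higher and 24 lower, or 253 and 122 with the set as a block. The block's 375 calls became 231, 164, 182 or 249 without the ICI array of set A or B or the Ral array of set A or B.

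With oestradiol present, the moderated F-test over the 3 antagonists at 8 h called a single probe set, of IER3 (268 at an unadjusted p under 0.05). IER3 stood at 1257 ± 56.5 with TOT against 320.4 ± 105 with Ral and 189 ± 15.8 with ICI. At 48 h it called 48 probe sets of 41 genes, which included KRT13, PTGES, OLFML2A, IGFBP4, CTSD, SOCS1 and TFF3. E2+TOT exceeded E2+Ral at 48 h in KRT13 (2.90, adjusted p = 2.14e-05), TFF1 (1660.0 ± 723 against 239.7 ± 128, adjusted p = 0.0359), IER3 (2.15) and CTSD (1.35), and fell below it in ZCCHC24 (-2.25), with 19 probe sets higher and 11 lower, or 48 and 45 with the set as a block.
Against E2+ICI, E2+TOT was higher in KRT13 (2.83), PTGES (2.47) and OLFML2A (2.42) and lower in ZCCHC24 (-3.02) and DDC (-1.98), with 34 probe sets higher and 28 lower, or 78 and 97 with the set as a block, and TFF1 did not pass (1.48, adjusted p = 0.406).
Between E2+Ral and E2+ICI limma called OLFML2A alone at 48 h (1.58, adjusted p = 0.0414, and 4 probe sets with the set as a block) and 0 at 8 h (451 at an unadjusted p under 0.05). At 48 h the 95% intervals were -2.52 to -0.10 for TFF1 and -0.76 to 0.06 for ESR1. The 48 of the F-test became 148 with the set as a block, and then 53 or 62 without the E2+TOT array of set A or B.

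The genes that oestradiol had called at 48 h also separated the antagonists, in comparisons chosen after the values were seen and corrected over 24 tests. With the compounds alone at 48 h, 336 of 376 such genes (89.4%) lay further toward their oestradiol direction with TOT than with ICI (median 0.55 in log2, adjusted p = 6.37e-06), and 325 (86.4%) did with Ral against ICI (0.38, adjusted p = 0.000183). So did 266 (70.7%) with TOT against Ral (0.16, adjusted p = 0.0410). With oestradiol present 274 (72.9%) lay further that way with TOT than with Ral (adjusted p = 0.0121), 281 (74.7%) with TOT than with ICI (adjusted p = 0.00580), and 200 (53.2%) with Ral than with ICI (adjusted p = 0.662). At 8 h without oestradiol, 106 of the 115 genes called at 8 h did so with TOT against ICI (92.2%, adjusted p = 0.00169), 104 with Ral against ICI (90.4%, adjusted p = 0.00169) and 52 with TOT against Ral (45.2%, adjusted p = 0.993). With oestradiol present at 8 h, 21 (18.3%) lay further toward their oestradiol direction with Ral than with ICI (adjusted p = 0.0483, away from it), and 32 (27.8%) with TOT than with ICI (adjusted p = 0.121), while 73 (63.5%) did with TOT against Ral (adjusted p = 0.605).

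**Figure D3:**
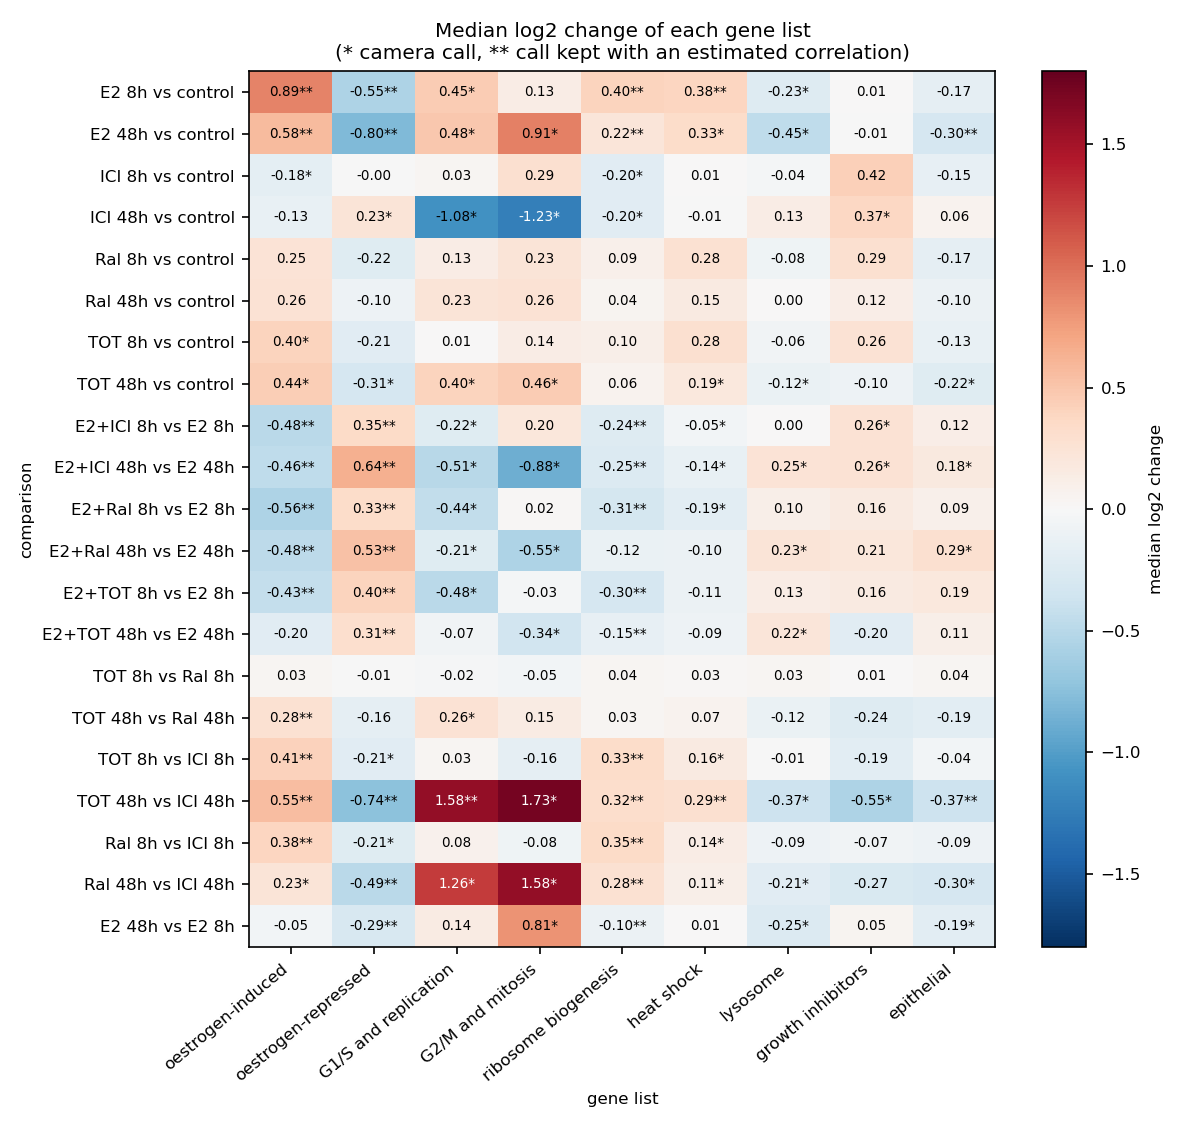
Median log2 change of 9 gene lists (columns) in 21 comparisons (rows), red for higher and blue for lower, with 1 asterisk for a camera call and 2 for a call kept with an estimated correlation. The cell cycle lists were lowest with ICI alone at 48 h against the control and highest with TOT against ICI at 48 h.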

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

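The tests of a difference between 48 and 8 h for each antagonist, alone or with oestradiol, and the tests on CYP1A1 and CYP1B1 were chosen after the values were seen, while the comparison of oestradiol at 48 and 8 h was planned. Each result of this part is listed because limma found a difference between the times within a treatment, given in log2 as 48 h minus 8 h, with the same sign in both sets for the genes named. The shared control arrays cancel in these differences, and no control array has a stated time. A change over time that the treatment did not make was therefore not removed, except where an antagonist with oestradiol was set against oestradiol at the same time.

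With oestradiol alone 24 probe sets differed between the times, or 187 with the set as a block. PEG10 was higher at 48 h by 1.8 (adjusted p = 0.0178), and the adhesion and matrix genes L1CAM (-2.79, adjusted p = 0.00137) and LAMB1 (-1.55, adjusted p = 0.00896) were lower, as was the calcium buffer gene PVALB (-2.26, adjusted p = 5.04e-05). With ICI alone 12 differed (145 with the set as a block), among them TK1 (-2.33, adjusted p = 0.0268) and PTTG1 (-2.35, adjusted p = 0.0164) of the cell cycle and the monooxygenase gene CYP1B1 (-1.73, adjusted p = 0.0164). With Ral alone 4 did, which included CYP1A1 (-3.57, adjusted p = 0.000208) and CYP1B1 (-2.82, adjusted p = 2.83e-05). With TOT alone the number was 20 (43 with the set as a block), and KRT13 (2.37, adjusted p = 0.000161) and RAB31 (1.38, adjusted p = 0.0134) were higher at 48 h while CYP1A1 (-4.26, adjusted p = 1.52e-05), CYP1B1 (-2.32, adjusted p = 0.000411), ZCCHC24 (-1.52, adjusted p = 0.0242) and PVALB (-1.42, adjusted p = 0.0134) were lower. The change an antagonist made with oestradiol present differed between the times in 4 probe sets for ICI, 3 for Ral and 4 for TOT. With the block the numbers were 14, 11 and 26. At an unadjusted p under 0.05 they were 360, 376 and 436, no more than by chance.

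CYP1A1 and CYP1B1 were higher than in the control arrays in every 8 h group without an added second compound. Handling or time shared by all 8 h arrays could not be the whole cause, since TOT exceeded ICI at 8 h by 2.64 in CYP1A1 (95% interval 1.70 to 3.58) and 1.88 in CYP1B1 (1.24 to 2.53), and both differences passed. For the part that ICI and oestradiol share (with ICI 2.48 for CYP1A1 and 2.26 for CYP1B1), a treatment effect and an effect of handling cannot be told apart, because no control array has a stated time. A wider response of the aryl hydrocarbon receptor stays open too, with 0 of 3 other tested targets called in TOT at 8 h (NQO1 0.47, TIPARP 0.62, ALDH3A1 -0.23). That Ral and TOT may act through this receptor at 8 h is a hypothesis found and tested on the same data.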

How the results depend on the processing

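The array quality weights, the tests of genes, lists and shares without control B, the block for list tests and for runs with an array left out, and the tests of degraded RNA and of a wrong label for control B were chosen after the values were seen, and the rest of this part was planned. Counts below are of probe sets called in limma, and where no reason is given the cause was not tested.

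With the set as a block, which takes the difference between the sets out of the residual spread, 20 of 23 counts moved by more than 1.5 times. Oestradiol then called 432 at 8 h and 997 at 48 h, and 187 between the times. ICI alone called 885 at 48 h, Ral alone 247 at 8 h and 65 at 48 h, and TOT alone 318 and 725. Added to oestradiol, ICI called 29 at 8 h and 450 at 48 h, Ral 68 and 298, and TOT 60 and 219. TOT against Ral gave 37 at 48 h, TOT against ICI 28 at 8 h and 814 at 48 h, Ral against ICI 17 and 375, and the test over the 3 antagonists with oestradiol 148 at 48 h. Of 434 results of named genes, 16 gained a call with the block, GREB1 with oestradiol at 8 h (2.34) and TFF1 with ICI alone at 48 h (-2.12) among them, and CSN2 lost its call with ICI at 8 h (-1.36). No other of the 434 changed. All 107 camera calls held, and further lists passed.

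Array quality weights gave each control array a weight of 0.362 and moved 13 of 23 counts. Oestradiol then called 26 at 8 h and 67 at 48 h, ICI alone 0 and 0, Ral alone 4 and 0, and TOT alone 9 and 24. In the presence of oestradiol, ICI at 8 h called 14 and TOT at 8 h 45, and the 3 antagonists differed in 4 at 8 h. TOT against ICI at 8 h gave 31, and Ral against ICI at 48 h 52.

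Using only the arrays compared leaves 2 or 3 residual degrees of freedom, so fewer probe sets pass. Against the control this called 19 and 48 with oestradiol at 8 and 48 h, 0 and 0 with ICI, 4 and 0 with Ral, and 5 and 2 with TOT, and 4 between the times of oestradiol. Added to oestradiol, ICI called 2 and 16 at 8 and 48 h, Ral 4 and 33, and TOT 2 and 18. TOT against Ral gave 0 and 0, TOT against ICI 8 and 28, Ral against ICI 3 and 3, and the 3 antagonists with oestradiol 9 at 48 h.

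Without the filter, ICI and TOT alone at 48 h called 27 and 130, E2+ICI at 8 h 2, TOT against Ral at 48 h 11, Ral against ICI 1 at 8 h and 48 at 48 h, and the 3 antagonists with oestradiol 2 at 8 h. In the upper 40% by intensity, ICI at 48 h called 322, TOT at 8 h 39 and TOT against Ral at 48 h 13. Without a variance trend, ICI at 48 h called 21, Ral at 48 h 1, TOT at 48 h 127, E2+TOT at 8 h 18, TOT against ICI at 8 h 10, and Ral against ICI 3 at 8 h and 47 at 48 h. With 1.7 as the added value, ICI at 48 h called 120, E2+ICI at 8 h 1 and Ral against ICI at 8 h 1, and with 22.35 ICI at 8 h called 3. Quantile normalization moved 2 of these counts, to 4 for Ral at 48 h and 5 for Ral against ICI at 8 h.

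Leaving out an array leaves a group of 1, assumed to vary like the others, and lets the difference between the sets enter. Counts against the control then ranged from 54 to 1149 for oestradiol at 8 h and 174 to 1311 at 48 h, 0 to 1128 and 0 to 1597 for ICI, 4 to 1415 and 0 to 1301 for Ral, and 8 to 1447 and 45 to 1505 for TOT, with each highest count reached without control A. The lowest was reached without control B for ICI, Ral at 48 h and TOT (0, 0, 0, 8 and 45), and also without the ICI array of set B for ICI (0 and 0), while for oestradiol it was reached without its set B array (54 and 174) and for Ral at 8 h without either of its arrays (4). Between the times of oestradiol the range was 5 to 35. With antagonists added to oestradiol, it was 0 to 8 and 59 to 98 for ICI, 7 to 22 and 52 to 63 for Ral, and 5 to 22 and 36 to 53 for TOT at 8 and 48 h. TOT against Ral gave 0 to 1 and 4 to 13, TOT against ICI 3 to 9 and 101 to 292, Ral against ICI 0 to 1 and 1 to 85, and the 3 antagonists with oestradiol 1 throughout at 8 h and 20 to 42 at 48 h.

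With the set as a block as well, which balances these runs only as far as the sets differ alike in all groups, counts against the control ranged from 114 to 1853 and 474 to 2010 for oestradiol at 8 and 48 h, 3 to 1937 and 55 to 2457 for ICI, 7 to 2237 and 5 to 2092 for Ral, and 12 to 2297 and 142 to 2289 for TOT. Each highest count was again reached without control A. The range between the times of oestradiol was 28 to 165. Added to oestradiol, ICI had 0 to 46 and 166 to 272, Ral 18 to 41 and 119 to 193, and TOT 17 to 48 and 81 to 127. TOT against Ral had 0 to 1 and 9 to 33, TOT against ICI 15 to 17 and 378 to 581, Ral against ICI 7 to 12 and 164 to 249, and the 3 antagonists with oestradiol 1 at 8 h and 53 to 118 at 48 h.

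The share of oestradiol-called genes that E2+ICI moved the other way at 8 h was 62.2% (adjusted p = 0.0538 in limma's fry). It was 62.3% after quantile normalization, where the unadjusted value fell below 0.05, 87.0% for genes called at 8 h, which share arrays with the test, and 85.3% for genes called without control B, or 77.6% with the set as a block as well.

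Among lists, the camera direction of ribosomal protein genes turned after quantile normalization, with the median going to -0.00103 from -0.22 in TOT at 8 h against the control, to 0.0131 from -0.22 in E2+ICI at 8 h, to -0.0116 from 0.12 in E2+Ral at 48 h and to 0.00996 from -0.11 in TOT against ICI at 8 h, with no camera call left. Of 107 camera calls, 66 were lost with an estimated correlation, 9 further ones weakened with quantile normalization and 3 with the mean of all probe sets of a gene, and 6 of 32 against the control were lost without control B, but only 1 with the set as a block as well. The 434 results of named genes, 167 of them against the control, include genes without a call, so shares lost among called genes were higher. Of the 434, 16 lost their call with quantile normalization, 18 with 1.7 as the added value and 13 with 22.35. With 22.35, TFF1 for E2+Ral at 8 h gained its call. Without control B, 54 of 167 lost theirs and 1 was added, against 30 and 7 with the set as a block as well.

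Control B lay apart from the other arrays, with a correlation of 0.945 with control A against 0.961 to 0.978 within other groups. Degraded RNA is argued against by its actin 3'/5' ratio of 1.06, within 0.972 to 1.27 of the other arrays, and scaling by the SD of its deviations after quantile normalization, 0.591 against 0.292 to 0.501. Cells given oestradiol alone under a control label are argued against by oestrogen-induced genes 0.118 (log2) above control A, against 0.641 to 0.919 in the 4 arrays with oestradiol alone. Arrays with oestradiol and an antagonist ran from 0.0927 to 0.824, so a mix-up with one of those is not excluded. What set it apart, a difference in the culture included, stays open, and which control array lies nearer to untreated cells may not be decided from 2 arrays.

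Intensities above background limit what can be said of weak genes. A gene near the bottom of the scale, such as IL1R1 after 48 h of oestradiol or CYP1A1 in the control arrays, has a fold change that depends on the value added before the logarithm, and PGR was not tested at all.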

Other observations

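The tests of ribosomal RNA carried over, of TOT against Ral with oestradiol, and of ICI with and without oestradiol, and of the blocks of samples, and the comparison of the sets, were chosen after the values were seen, while the test of scaling between the sets was planned. Between set A and set B, averaged over the 15 groups, 2522 of 8791 probe sets differed in limma (1086 higher in set B and 1436 lower). Sterol and fatty acid synthesis genes were higher in set B. The mevalonate pathway gene MVD stood at 59.5 in set A and 269.6 in set B (log2 difference 2.23), the isomerase gene IDI1 at 1421 and 2595, the master regulator SREBF1 at 1075 and 2179, its partner INSIG1 at 628 and 1100.1, and the fatty acid synthase gene FASN at 2108 and 3491. The cholesterol list lay above 0 in 15 of 15 groups (median 0.57, from 0.14 to 0.94), as did the fatty acid list (0.54, from 0.20 to 0.74) and the lysosome list (0.23). With all arrays each group held both sets, so the set difference cancelled in every treatment contrast, but it did not where an array was left out without the set as a block.

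Genes of the cell cycle differed the other way. CDK1, the mitotic kinase gene, stood at 341 in set A and 165 in set B, the thymidylate synthase gene TYMS at 1264 and 721, and the lamin gene LMNB1 at 1104 and 591. G2/M and mitosis genes were lower in set B in 15 of 15 groups (median -0.60) and G1/S and replication genes in 14 of 15 (-0.43).

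Ribosomal RNA carried over in set A, where 18S signals reached 814, is argued against as the whole cause by the 3 groups whose set A array was as low in 18S as set B, in which the G2/M excess of set A was still at least 0.612. Scaling is argued against by an excess of 0.612 after quantile normalization (median over groups, from 0.0319 to 0.996). If the sets were separate cultures, a difference in growth or lipid supply may lie behind both shifts, but the labels do not say what the sets are, so no biological explanation was tested.

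The difference between TOT and Ral at 48 h may not depend on the absence of oestradiol. Of the 20 probe sets called between the compounds alone, 19 had the same sign with oestradiol present, in arrays not shared, and 15 were called there. KRT13, TFF1, IER3 and PTGES were higher with TOT in both settings. This remains a hypothesis tested on the data in which it was seen.

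At 48 h, ICI without oestradiol left cell cycle genes lower than ICI with oestradiol. The 71 genes of both lists lay lower in ICI alone than in E2+ICI, with a median difference of -1.24 (-1.32 in set A and -1.16 in set B), though limma called only 10 of them. These groups lie in different blocks of the sample list, so a batch difference between the blocks may enter. One shared by both times is argued against as the whole cause by the change from 8 to 48 h, where ICI alone minus E2+ICI had a median of -1.15 (-1.35 in set A and -1.01 in set B). For that difference limma called 0 of the 71 genes, or 22 with the set as a block, and a batch difference in the 48 h arrays alone stays open. The median of the 71 genes in E2+ICI at 48 h against the control was 0.07, and between ICI at 48 and 8 h it was -1.35, a difference that involves no control array. Whether the fall occurs only without oestradiol stays open. With oestradiol present, 69 of the 71 genes lay lower with ICI than without it (median -0.659, -0.46 in set A and -0.89 in set B), from a level that oestradiol alone had put 0.78 above the control, though neither list passed there with an estimated correlation (adjusted p = 0.503 and 0.481). Each group held 2 arrays, and with the set as a block the 885 calls against the control fell to 69 without control B.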
